A study of Homo sapiens with 4 samples.

How the data were processed

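Polyadenylated RNA from H9 cells was sequenced in 4 libraries, 2 from control cells and 2 from cells with SLC35F2 knocked out, and each library was placed in its group by its title. Per the labels' protocols, RNA was isolated with Trizol and column purification and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the authors used FastQC 0.11.7, cutadapt 1.8.1, STAR 2.6.0a and HTSeq 0.11.0 with the GRCh38 (hg38) build. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be fully separated. The deposited values are whole-number read counts per gene, not normalised, for 60483 Ensembl gene identifiers per library. The labels' protocols also mention quantile normalisation, but whole numbers with unequal library totals do not carry it, and it was tried as an alternative.

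Reads that the authors' counting gave to no single gene were left out of library sizes and tests. They made up 17.8% of the counted alignments in control 1, 20.3% in control 2, 16.7% in KO 1 and 14.4% in KO 2. Reads outside annotated features were 8.40%, 10.8%, 7.41% and 4.59% in the same order, and mitochondrially encoded genes took 7.38%, 6.49%, 5.15% and 8.97% of the assigned reads. Assigned reads ranged from 27824693 to 37978705 per library. Gene names, positions and biotypes came from GENCODE 29 on GRCh38, in which 56753 identifiers (93.8%) matched without their version suffix, and from tables of current gene symbols. The stress genes XBP1 and HSPA1A are listed at 0 reads in all 4 libraries, which can reflect how reads were counted, so their absence from a list says nothing of the cells.

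Genes with too few reads were removed with edgeR's filterByExpr (minimum count 10), leaving 19027. TMM factors scaled the libraries, and CPM values use these factors. KO was compared with control with edgeR 4.0.16 (quasi-likelihood F test, robust dispersions, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of F, and 95% intervals from the t distribution with the model's degrees of freedom. The common dispersion was 0.132, a biological coefficient of variation of 36.3%. In the model the replicate number was not a term, since no label says that it marks a shared day or culture. Replicates were compared by a chi-square test of their counts, which gave 62.0 per degree of freedom between the controls and 134 between the KO libraries, so no library was a copy of another.

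The design, the tests, the alternatives, 25 gene lists and the rule for naming genes were set before the data were examined. The first fit that was run used edgeR's legacy default and called 1 gene. The alternatives set beforehand name the edgeR 4 fit as the main one, which called 5, but both counts were known when this was settled. The lists reported covered core pluripotency, the naive state, neuroectoderm, mesoderm and primitive streak, endoderm, trophoblast and amnion, neural crest, fibroblast and stromal cells, queuosine modification, SLC35F and nucleoside transporters, the BCL2 family and inhibitors of apoptosis, cell cycle, stress responses, hypoxia and glycolysis, interferon response, imprinted genes, the 20q segment, Nodal and TGF-beta targets, WNT targets, cholesterol synthesis, immediate early and heat shock genes, mitochondrially encoded genes, replication histones and metallothioneins. A gene was named if it was SLC35F2, POU5F1, NANOG, SOX2, LIN28A, DNMT3B, BIRC5 or BCL2L1, or if it was among the 12 largest rises or 12 largest falls of called protein-coding genes with a mean of at least 2 CPM whose groups did not overlap. From each list up to 3 called members with the smallest p were named, or else the 2 most abundant members. Some genes under this rule and 1 of the lists are not reported here. Other named genes are said to be chosen after their values were seen. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), with camera using an estimated correlation and with fry, from limma 3.58.1. Each chromosome's genes were tested as a set in the same way.

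The alternatives were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom, quantile normalisation with limma-trend, the legacy quasi-likelihood fit, other filters on low counts, the replicate number as a block, each library left out in turn, counts thinned to the smallest library and a threshold of 0.01. Library weights in limma-voom and a correction for transcript GC content were added after the data were seen. The main test was tested on simulated counts drawn from these libraries' means, sizes and dispersions with 200 genes changed. Of 18397 simulated genes tested, it recovered 5 of 50 changed 2-fold, 38 of 50 changed 4-fold and 50 of 50 changed 8-fold or 32-fold, with 15 unchanged genes called. With a far smaller dispersion it recovered 48 of 50 changed 2-fold, with 18 unchanged genes called. In both simulations the unchanged genes made up a larger share of the calls than the threshold of 0.05 aims at. The main test's adjusted p-values may therefore be somewhat too small. Camera called a list shifted 4-fold and placed 3 of 100 random lists at an unadjusted p under 0.05. That run used the far smaller dispersion and drew each gene independently. It therefore cannot test the preset correlation of 0.01 for lists whose members vary together. At the depth and spread of the real libraries, 2-fold differences were mostly below what the main test could call in simulation. The recovery of larger simulated changes does not carry over to the real libraries, where far larger differences were missed too. Among them, MT1G was 61.3-fold lower in KO (edgeR adjusted p = 0.162) and MT2A 49.0-fold lower (edgeR adjusted p = 0.195).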

Results

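RNA was measured by poly(A)-selected sequencing in H9 cells, also called WA09, an established human embryonic stem cell line. The samples were 2 control libraries and 2 libraries from cells in which SLC35F2 was knocked out (KO). SLC35F2 encodes a solute carrier of the cell membrane, known as the carrier through which the compound YM155 enters cells and also described as a carrier of queuine, the base that is built into queuosine in certain transfer RNAs. Control 1 held 37978705 reads assigned to genes, control 2 held 32423108, KO 1 held 27824693 and KO 2 held 36943597. The labels do not say whether the libraries of a group came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical. The single comparison of the design, KO against control, asks how the RNA profile of these stem cells differs after loss of SLC35F2.

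The targeted gene was lower in both KO libraries. SLC35F2 (ENSG00000110660.13, chromosome 11, 107790991 to 107928293 on the minus strand of GRCh38, protein coding) had a normalised level of 41.1 CPM (reads of the gene relative to the scaled library total) in control 1 and 27.1 in control 2, against 12.1 in KO 1 and 9.65 in KO 2. These values came from 1550, 964, 332 and 330 reads. The group means were 34.1 ± 9.86 CPM (SD, n = 2) in control and 10.9 ± 1.71 CPM (SD, n = 2) in KO, a log2 fold change of -1.65 ± 0.35 (SE) with a 95% confidence interval from -2.46 to -0.85. Over all genes tested its Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test was 0.58. Taken alone, as the gene fixed beforehand, it had an unadjusted p of 0.00124 in edgeR's model across all genes. The libraries therefore stood on the sides that their labels give, with SLC35F2 RNA still present in both KO libraries. Over all genes SLC35F2 was called in 4 of 18 alternative settings, among them DESeq2 (adjusted p = 0.00843) and the replicate block (0.00736). The other calls came without KO 1 (log2 fold change -1.81) and without KO 2 (-1.50). There the lone KO library is assumed to vary as the controls do. SLC35F2 was not called in the remaining settings, with an adjusted p of 0.837 in limma-voom. Those settings included leaving out control 1 (log2 fold change -1.31) and control 2 (-1.92).

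The metallothioneins had the smallest adjusted p of the 25 gene lists in camera's test with a preset correlation. No list passed with an estimated correlation, where the metallothioneins had a camera adjusted p of 0.431. These genes, which encode small cysteine-rich proteins that bind zinc and copper, had a summed level of 273 CPM in control 1 and 704 CPM in control 2, against 18.5 CPM in KO 1 and 6.67 CPM in KO 2. The means, 489 ± 305 CPM (SD, n = 2) in control and 12.6 ± 8.37 CPM (SD, n = 2) in KO, differed 38.8-fold. SLC30A1, which encodes the zinc exporter of the plasma membrane, was 6.25-fold lower in KO, and PKIB, an inhibitor of protein kinase A, was 7.83-fold higher. The 5 calls over all genes were 2 metallothioneins, SLC30A1, PKIB and the long non-coding RNA AC003975.1.

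Of 19027 genes tested, 5 passed the adjusted threshold of 0.05 in edgeR's quasi-likelihood test, 4 lower and 1 higher in KO, and all 5 differed at least 2-fold. Where no other tool or setting is named, a gene is said to be called by this test. A call adjusted over a list alone adjusts the same p-values within that list and does not correct for the 25 lists. MT1H fell by 8.0 ± 0.69 (SE) on the log2 scale, from 55.0 ± 31.8 to 0.219 ± 0.102 CPM (SD, n = 2 per group; edgeR adjusted p = 0.022). MT1E fell by 5.94 ± 0.58 (SE), from 67.4 ± 33.0 to 1.13 ± 0.769 CPM (edgeR adjusted p = 0.0315). SLC30A1 (chromosome 1, 211571568 to 211578742, minus strand) fell by 2.64 ± 0.28 (SE), with 174 and 211 CPM in the controls and 32.9 and 28.7 CPM in the KO libraries (edgeR adjusted p = 0.0315). AC003975.1 (chromosome 7, 125917871 to 125933832, plus strand), annotated as a long intergenic non-coding RNA and named after its values were seen, had 40.4 and 58.5 CPM in control and 4.51 and 3.77 CPM in KO (log2 fold change -3.58 ± 0.37, edgeR adjusted p = 0.0315). PKIB (chromosome 6, 122471917 to 122726373, plus strand) rose from 6.10 and 5.57 CPM to 47.0 and 44.4 CPM, a log2 fold change of 2.97 ± 0.32 (edgeR adjusted p = 0.0315).

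The 5 calls did not hold under every setting. Without control 1 SLC30A1 (adjusted p = 0.133), AC003975.1 (0.133) and PKIB (0.361) were no longer called, and without control 2 their adjusted p-values were 0.0627, 0.155 and 0.269, while MT1H and MT1E were called in both cases. With upper-quartile scaling, with library size only, with limma-voom and with genes of a mean CPM under 1 left out, 0 genes were called. In this order 801, 787, 692 and 523 genes had an unadjusted p under 0.05. The filter setting tested 15075 genes and the others 19027, for which 951 are expected by chance. None of these counts exceeded the share expected by chance. The adjusted p-values of the 5 genes were then 0.0511 to 0.0628 with upper-quartile scaling and 0.0882 to 0.096 with library size only. They were 0.117 to 0.119 in limma-voom and 0.0554 with the filter on mean CPM. DESeq2 called 60 genes, 56 lower and 4 higher. At an unadjusted p under 0.05, edgeR placed 773 genes, 202 higher and 571 lower, against 951 expected by chance.

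**Figure D1:**
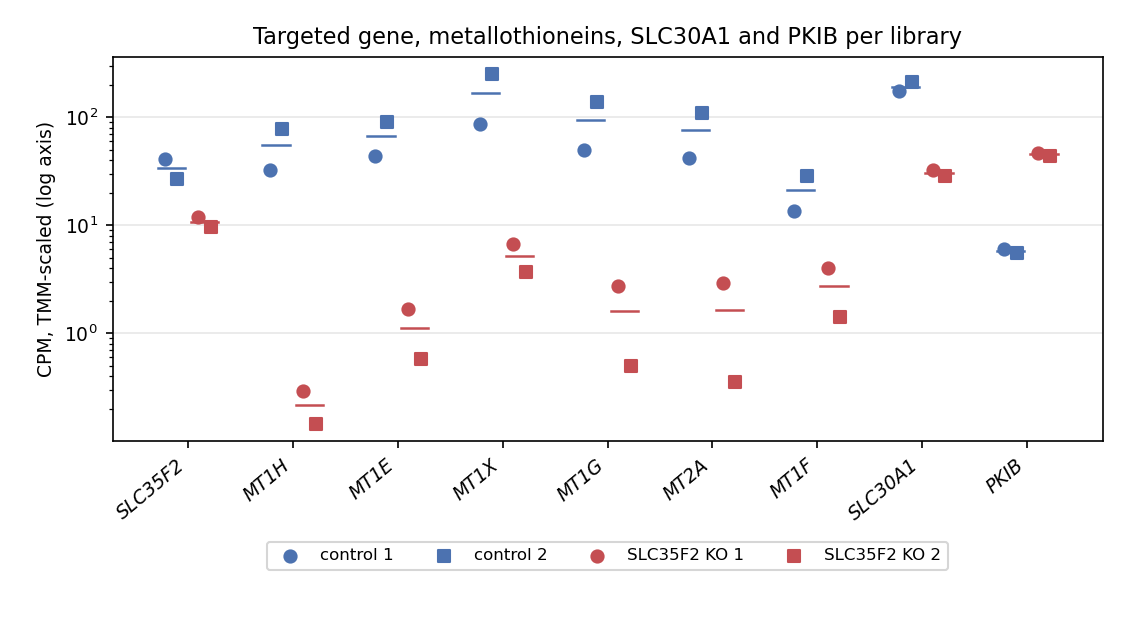
Each point is the TMM-scaled CPM of 1 library on a log axis for the targeted gene SLC35F2, 6 metallothioneins, SLC30A1 and PKIB, with circles for replicate 1, squares for replicate 2, blue for control, red for KO and a short line at each group's mean. Both KO points lie below both control points for each gene shown except PKIB, where 47.0 and 44.4 CPM in KO lie above 6.10 and 5.57 CPM in control.

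All 7 metallothioneins with enough reads to be tested were lower in both KO libraries than in both controls. Of these, edgeR called 2 over all genes and 7 adjusted over the list alone. Over 18 alternative settings the number called over all genes ranged from 0, with limma-voom, upper-quartile factors and library size only among others, to 7 with DESeq2 and with either KO library left out. MT1X, the most abundant, had 87.9 and 252 CPM in control against 6.76 and 3.69 CPM in KO. MT2A had 42.0 and 111 CPM against 2.91 and 0.351 CPM, and MT1G had 49.6 and 141 CPM against 2.73 and 0.497 CPM. MT1F differed by a log2 fold change of -2.98 ± 0.59, and MT1M had 122 and 151 reads in control against 2 and 0 in KO. These members were named after their values were seen. The median log2 fold change of the list was -5.94, and camera's set test gave an adjusted p of 8.89e-66. With an estimated correlation between members the list did not pass (adjusted p = 0.431 with an estimated correlation). The genes lie together on chromosome 16 (56589074 to 56684196) and have near-identical sequences, so the split of reads among single members is uncertain. The summed level, taken over the 7 tested members, does not depend on how assigned reads were split. It can depend on reads that matched several genes, which were left out of the counts. Among other genes of zinc handling MTF1, the transcription factor that responds to zinc, was not called and had 19.2 and 21.9 CPM in control and 19.2 and 18.3 CPM in KO (log2 fold change -0.13, 95% confidence interval -0.85 to 0.59). The zinc importers SLC39A10 (0.25, interval -0.70 to 1.2) and SLC39A14 (-0.29, interval -1.27 to 0.70) were not called either. MTF1, SLC39A10 and SLC39A14 were chosen after their values were seen.

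The main transcription factors of pluripotency were present in all 4 libraries, and none of them was called. POU5F1 had 282 and 306 CPM in control and 401 and 227 CPM in KO (log2 fold change 0.09, 95% confidence interval -0.62 to 0.81). Its sign turned with library size only, which moved the median log2 fold change of all genes from 0.029 to -0.097, and with quantile normalisation. SOX2 had a log2 fold change of 0.15 (interval -0.45 to 0.75), and the RNA-binding protein gene LIN28A one of 0.20 (interval -0.35 to 0.75), which turned to -0.0055 with quantile normalisation. NANOG had 61.2 and 64.7 CPM in control and 46.2 and 19.1 CPM in KO. Its log2 fold change was -0.95 (interval -1.87 to -0.03) with an unadjusted p of 0.0438 and an adjusted p of 0.997 in edgeR. The DNA methyltransferase gene DNMT3B had 1743 and 1302 CPM in control, 1550 CPM in KO 1 and 662 CPM in KO 2. Without KO 1 the log2 fold changes of NANOG and DNMT3B were -1.71 and -1.19, and without KO 2 they were -0.44 and 0.028. In these fits the lone KO library is assumed to vary as the controls do.

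Of all genes tested, 16.3% were lower and 15.8% higher in both KO libraries than in both controls, which is the background for such counts in a list. The core pluripotency list passed camera's test with a preset correlation as lower in KO. Of its 27 members, 12 were lower and 1 was higher in both KO libraries, while 14 overlapped between the groups. Its median log2 fold change was -0.20, with a camera adjusted p of 1.36e-05 and an adjusted p of 0.616 with an estimated correlation. The list's mean was -0.69, with HHLA1 (-4.57) and LINC-ROR (-4.38) far below the median. In edgeR's main test no member was called over all genes, and 2 were called adjusted over the list alone, HHLA1 and the non-coding RNA LINC-ROR. Over all genes DESeq2 called LINC-ROR (adjusted p = 3.06e-06) and not HHLA1 (0.27), and the replicate block called both. HHLA1, whose transcripts in human stem cells begin in an endogenous retrovirus, had 31.2 and 21.8 CPM in control against 2.18 and 0.175 CPM in KO (log2 fold change -4.57 ± 0.74, edgeR adjusted p = 0.195). LINC-ROR had 6.07 and 5.69 CPM against 0.509 and 0.0877 CPM. ESRG, a non-coding RNA abundant in pluripotent cells, had 831 and 1125 CPM in control, 635 CPM in KO 1 and 321 CPM in KO 2. PODXL, a surface sialomucin of stem cells, had a log2 fold change of -0.29 (interval -0.92 to 0.33). Averaged over the list as log2 differences from the control mean, KO 1 stood at -0.37 and KO 2 at -1.14, and without KO 2 the list was not called (adjusted p = 0.125). HHLA1, LINC-ROR and ESRG were named after their values were seen.

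**Figure D2:**
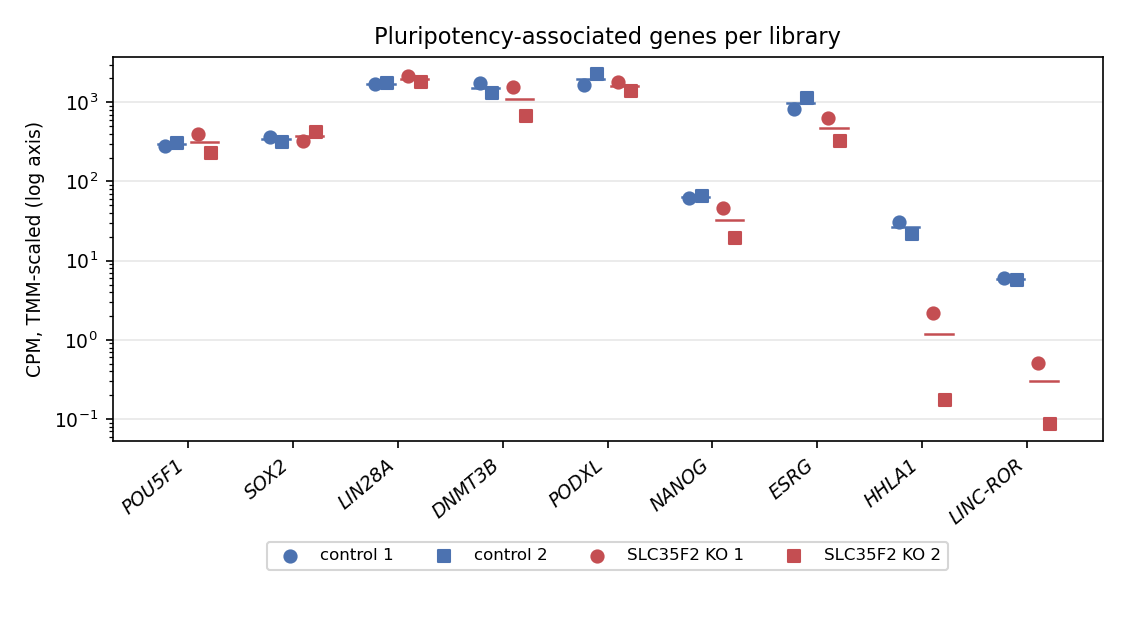
Each point is the TMM-scaled CPM of 1 library on a log axis for 9 genes linked to pluripotency, with circles for replicate 1, squares for replicate 2, blue for control, red for KO and a short line at each group's mean. POU5F1, SOX2, LIN28A and PODXL overlap or nearly overlap between the groups, whereas HHLA1 and LINC-ROR lie lower in both KO libraries and lowest in KO 2.

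The lists of differentiated lineages that passed the set test did so as lower in KO, although not each was lower in both KO libraries than in both controls. Of the mesoderm and primitive streak list, 11 of 26 members had enough reads to be tested, and 5 of those were lower in both KO libraries (median log2 fold change -1.01, camera adjusted p = 7.2e-06, and adjusted p = 0.431 with an estimated correlation). KDR, the receptor VEGFR2, had 280 and 294 CPM in control and 154 and 131 CPM in KO (log2 fold change -1.01 ± 0.26), and CDX2, a caudal-type homeobox factor, had 16 and 11 reads in control and 0 in both KO libraries, at least 7.54-fold lower against a floor of 3 reads over the group. Both were called by edgeR adjusted over the list alone and not over all genes. BMP4 had a log2 fold change of -0.31 (interval -1.82 to 1.2). The trophoblast and amnion list was lower too, with 4 of its 12 tested members lower and 3 higher in both KO libraries (median log2 fold change -0.45, camera adjusted p = 0.0488, and adjusted p = 0.616 with an estimated correlation). GATA2 had 8.58 CPM in control 2, 0.504 CPM in control 1 and 0.109 and 0.146 CPM in KO, with no call by edgeR but calls over all genes by DESeq2 (adjusted p = 0.00243) and with the replicate block (0.00338). KRT7 had a log2 fold change of 0.32 and IGFBP3 one of -1.15. The neural crest list (11 tested, 2 lower in both KO libraries) had a median of -0.21 and a camera adjusted p of 0.0397, and an adjusted p of 0.616 with an estimated correlation. Among its most abundant members, ERBB3 had a log2 fold change of 0.27 (interval -0.36 to 0.90) and was not called. The fibroblast and stromal list (22 tested, 4 lower in both KO libraries) had a median of -0.21 and a camera adjusted p of 0.0397, and an adjusted p of 0.667 with an estimated correlation. In the neural crest and fibroblast lists the share of members lower in both KO libraries was near the 16.3% of all genes. THY1 (0.19) and SPARC (-0.06), the most abundant fibroblast members, were not called, and the sign of SPARC turned after a correction for GC content. The naive state list (8 of 18 members tested, 3 lower in both KO libraries) had a median of -0.79 and a camera adjusted p of 0.00442, and an adjusted p of 0.616 with an estimated correlation. SUSD2, a surface marker of naive cells, had a log2 fold change of -0.61 and TFCP2L1 one of -0.37, with no call.

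The lineage lists differed in how far they rested on single libraries. As means of log2 differences from the control mean, the trophoblast list stood at -0.56 in control 1 and -0.49 in KO 2. The fibroblast list stood at -0.22 in control 1 and 0.097 in KO 2, so KO 2 was not below control 1 in either. Mesoderm stood at -0.33 in control 1, -1.27 in KO 1 and -1.19 in KO 2. In the same order the naive state stood at -0.29, -1.30 and -0.70, and neural crest at -0.30, -0.87 and -0.36. Both KO libraries were thus below control 1 in these lists, though only slightly for KO 2 in neural crest. Without KO 1 the adjusted p was 0.197 for mesoderm, 0.197 for trophoblast, 0.38 for neural crest and 0.251 for the naive state, and the fibroblast list changed its direction to higher (adjusted p = 0.453). Without control 2 the adjusted p was 0.683 for trophoblast, neural crest and fibroblast and 0.62 for the naive state, while mesoderm was still called (0.0318). Over 18 alternative settings of the set test with a preset correlation, the call of the trophoblast list held in 7, of neural crest in 8 and of fibroblast in 14, and over 17 settings mesoderm held in 16 and the naive state in 13. The setting missing for mesoderm and the naive state was a mean CPM of at least 5, which left fewer than 3 members. BMP4, the most abundant tested mesoderm member after KDR, had a mean of 4.70 CPM. The mesoderm call thus rests mostly on genes under 5 CPM and could not be tested above that level. Trophoblast and neural crest were both lost with limma-voom, quantile normalisation, every other filter on low counts, library weights and shared members left out, and trophoblast also with upper-quartile factors and library size only. Neural crest was also lost after thinning, fibroblast with no filter and with library weights, and the naive state with no filter and with a mean CPM of at least 1.

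Lists of genes that respond to signalling and stress passed the set test as lower in KO, and control 2 held their highest mean levels. Relative to the control mean, the immediate early list stood at -0.77 in control 1, -1.46 in KO 1 and -0.49 in KO 2, so KO 2 was above control 1. The list of the integrated stress and unfolded protein responses stood at -0.31, -0.41 and -0.35 in the same order. The immediate early and heat shock list had 8 of its 22 tested members lower and 2 higher in both KO libraries (median log2 fold change -1.18, camera adjusted p = 0.000151, and adjusted p = 0.616 with an estimated correlation). FOS had 24.8 CPM in control 1, 176 CPM in control 2, 5.89 CPM in KO 1 and 20.6 CPM in KO 2, and EGR1 had 85.9, 446, 14.9 and 76.0 CPM. Neither was called by edgeR's main test (adjusted p = 0.997 for both) or by DESeq2, whereas the replicate block called FOS (9.24e-06) and EGR1 (1.55e-06), although no label says that a replicate number pairs the libraries. The chaperone gene HSPA8 went the other way, with a log2 fold change of 0.78 (interval 0.13 to 1.43) and an edgeR adjusted p of 0.997. The list was no longer called without control 2 (adjusted p = 0.683) or without KO 1 (0.251). The Nodal and TGF-beta target list had 5 of 17 members lower in both KO libraries (median -0.37, camera adjusted p = 0.000151, and adjusted p = 0.616 with an estimated correlation). Its members SMAD7, ID1 and BAMBI, feedback regulators and a dominant-negative helix-loop-helix factor of these pathways, were called by edgeR adjusted over the list alone and not over all genes. DESeq2 called all 3 over all genes, with adjusted p-values of 0.049, 0.039 and 0.0171. SMAD7 had 27.1 and 53.3 CPM in control against 15.2 and 9.39 CPM in KO, ID1 had 92.8 and 177 CPM against 29.9 and 52.8 CPM, and BAMBI had 16.5 and 29.6 CPM against 7.16 and 6.79 CPM. ID3 had a log2 fold change of -1.16 and the Nodal co-receptor gene TDGF1 one of -0.20, and the list was not called without KO 1 (adjusted p = 0.0539).

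The WNT target list had 4 of 12 members lower in both KO libraries (median -0.53, camera adjusted p = 0.0397, and adjusted p = 0.616 with an estimated correlation). AXIN2 (-0.69, interval -1.64 to 0.25) and TCF7 (-0.86, interval -1.76 to 0.03) were not called. The list of the integrated stress and unfolded protein responses had 6 of 24 members lower and 1 higher in both KO libraries (median -0.28, camera adjusted p = 0.00654, and adjusted p = 0.616 with an estimated correlation). The chaperone genes HSP90B1 (-0.24) and CALR (0.05) were not called, and the sign of CALR turned with upper-quartile factors, library size only and quantile normalisation. Without control 2 both lists had an adjusted p of 0.62, and without KO 1 they had 0.251 and 0.119. Over 18 alternative settings the call of the WNT list held in 7 and that of the stress list in 16. The WNT list was also lost with upper-quartile factors, library size only, limma-voom, quantile normalisation, no filter, a mean CPM of at least 1, thinning, library weights and shared members left out. FOS, EGR1, GATA2, SMAD7, ID1, BAMBI, KDR and CDX2 were picked out after their values were seen, although each belongs to a list fixed beforehand.

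The survival genes of the BCL2 family and the genes of cell division showed no call over all genes in edgeR's main test. The cell cycle list passed as higher, although the 4 of its 27 members higher in both KO libraries were no more than the share of all genes (15.8%), and 2 were lower in both (median 0.24, camera adjusted p = 0.036, and adjusted p = 0.616 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, had 474 and 534 CPM in control, 470 CPM in KO 1 and 755 CPM in KO 2, and the replication helicase gene MCM3 had a log2 fold change of 0.10, whose sign turned with library size only and with quantile normalisation. The list was not called without control 2 (adjusted p = 0.62), without KO 1 (0.106) or without KO 2 (0.15), and its call held in 11 of 18 alternative settings. It was also lost with library size only, quantile normalisation and a mean CPM of at least 1 or at least 5. BIRC5, which encodes survivin, the protein whose expression YM155 lowers, had 162 and 142 CPM in control and 174 and 192 CPM in KO (log2 fold change 0.27, interval -0.31 to 0.85). BCL2L1, a gene that blocks apoptosis, had 53.9 and 52.3 CPM against 64.9 and 83.6 CPM (0.48, interval -0.14 to 1.11). The list of the BCL2 family and the inhibitors of apoptosis, with 9 of 24 members higher and 3 lower in both KO libraries, did not pass (median 0.26, camera adjusted p = 0.229). Its members MCL1 (-0.54) and PMAIP1 (-0.83, interval -1.52 to -0.14) were not called. CDKN1A, an inhibitor of cyclin-dependent kinases named after its values were seen, had 9.25 and 21 CPM in control, 3.96 CPM in KO 1 and 29.8 CPM in KO 2.

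The genes around queuosine and nucleoside transport contained 1 large difference. QNG1, the enzyme that frees queuine from queuosine nucleosides, had 2.44 and 2.48 CPM in control (92 and 88 reads) and 0.109 and 0.0292 CPM in KO (3 and 1 reads). Its log2 fold change of -5.16 ± 0.86 was called by edgeR adjusted over the list alone and not over all genes (edgeR adjusted p = 0.162), while DESeq2 called it over all genes (0.00026), and it was named after its values were seen. QTRT1 (0.13, interval -0.73 to 0.99) and QTRT2 (-0.15, interval -0.87 to 0.57), the subunits of the enzyme that inserts queuine into transfer RNA, were not called, and quantile normalisation turned the sign of QTRT1. Over its 5 members the list did not pass (camera adjusted p = 0.103, direction lower), with a median of 0.05 and a mean of -0.88 that differ in sign. The list of other SLC35F and nucleoside transporters did not pass (15 tested, median 0.13, camera adjusted p = 0.177), with SLC29A1, the equilibrative nucleoside transporter, at 0.31 (interval -0.29 to 0.91) and SLC35B4 at 0.09, which turned below 0 with library size only and with quantile normalisation.

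Metabolic, interferon, imprinted and remaining lineage lists did not pass the set test. Hypoxia and glycolysis genes (23 tested) had a median of 0.26 and a camera adjusted p of 0.573. Their member ADM, the peptide hormone adrenomedullin, had 130 and 301 CPM in control against 63.0 and 53.6 CPM in KO and was called by edgeR adjusted over the list alone and by DESeq2 over all genes (adjusted p = 0.00759), while ENO1 (0.25) and ALDOA (0.51) were not called. Cholesterol synthesis genes (22 tested, median 0.14, camera adjusted p = 0.229) included FDFT1 at 0.01. Mitochondrially encoded genes (13 tested) had a median of 0.15 and a camera adjusted p of 0.174, which was 0.0446 after the GC correction, with MT-CO1 at 10302 CPM in KO 1 and 23847 CPM in KO 2. Interferon response genes (20 tested) had a median of 0.16 and a camera adjusted p of 0.563, with IFITM1 at 130 and 167 CPM in control, 59.7 CPM in KO 1 and 275 CPM in KO 2, and IFITM3 at 0.19. Imprinted genes (22 tested, camera adjusted p = 0.486 and direction lower) had a median of 0.12 and a mean of 0.06, opposite in sign to the test, with GNAS at 0.18 and SNRPN at 0.12. Endoderm genes (13 tested, camera adjusted p = 0.486 and direction lower) had a median of 0.04 and a mean of -0.16, with CLDN6 at 0.30 and FOXA3 at 0.23. Neuroectoderm genes (18 tested, camera adjusted p = 0.849 and direction lower) had a median of 0.14 and a mean of 0.33, with NES at 0.22 and OTX2 at 0.35. Replication histone genes, whose RNA mostly lacks poly(A), had a median of -0.28 over 15 tested members and a camera adjusted p of 0.486, with H2AC6 at -1.40 and H1-2 at -0.54.

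Genes of the 20q segment that is often gained in cultured stem cells were higher as a list, and the difference came from KO 2. Of 19 tested members, 9 were higher and 1 was lower in both KO libraries (median 0.44, camera adjusted p = 0.0148, and adjusted p = 0.626 with an estimated correlation). TPX2, a spindle assembly factor, had 162 and 182 CPM in control, 179 CPM in KO 1 and 435 CPM in KO 2. Averaged over the list as log2 differences from the control mean, KO 1 stood at -0.10 and KO 2 at 0.53, and without KO 2 the list was not called (adjusted p = 0.904). It was also lost with quantile normalisation (0.0802) and with a mean CPM of at least 5 (0.106). ID1, the member called adjusted over the list alone, and DNMT3B were lower in KO 2 than in both controls. With each of 23 chromosomes tested as a set, 0 passed, and the smallest adjusted p was 0.578 with camera.

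**Figure D3:**
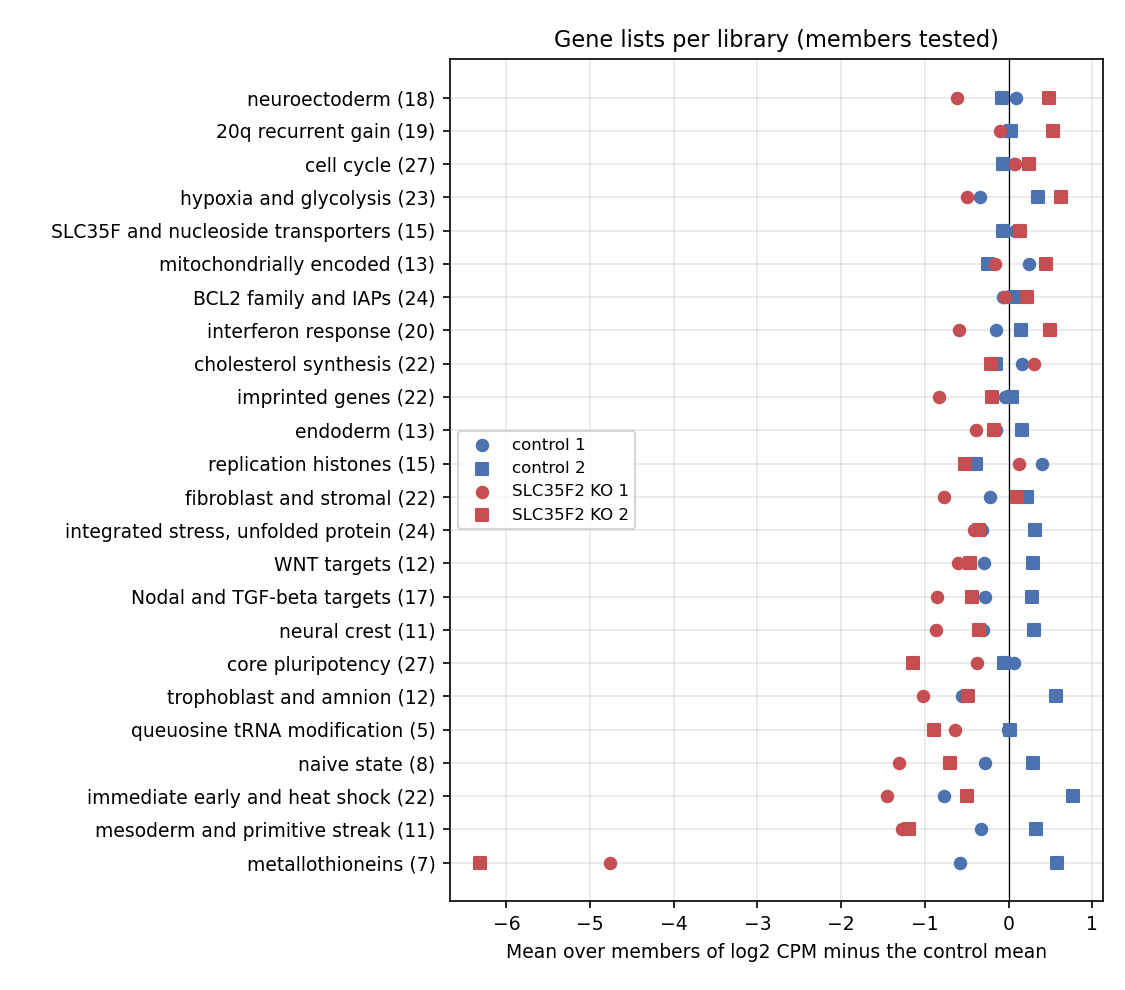
Each point is the mean over a list's tested members of the log2 CPM of 1 library minus the control mean, with the number of members in brackets, circles for replicate 1, squares for replicate 2, blue for control and red for KO. The metallothioneins stand apart at -4.76 in KO 1 and -6.32 in KO 2, core pluripotency lies at -0.37 and -1.14, and the 20q list at -0.10 and 0.53.

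The libraries differed within groups as well as between them. Across genes, Pearson's r of log2 CPM was 0.977 between the controls and 0.944 between the KO libraries, while control 1 and KO 1 had 0.982, the highest of the 6 pairs, and genes are not independent replicates. Of 11570 genes with a mean of at least 5 CPM, 3.65% differed at least 2-fold between the controls and 14.1% between the KO libraries. Leaving out either KO library raised the number of called genes, to 1096 without KO 1 and 188 without KO 2, where the remaining KO library is assumed to vary as the controls do. All 13 list calls came from camera with a preset correlation, 0 lists passed with an estimated correlation (smallest adjusted p = 0.431), and 0 passed with fry.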

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

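The alternatives of library weights and of a GC correction were chosen after seeing the data, and the others before. MT1H, MT1E, SLC30A1, PKIB and AC003975.1 kept their direction in all 18 settings that refit the genes. MT1H was past the threshold in 12 of them, MT1E in 10 and the other three in 8. The metallothionein list was called in all 18 settings of the set test with a preset correlation. These settings share the preset correlation of 0.01, where 0.938 was estimated for this list, so they do not test that assumption. RLE factors and thinning each gave 5 calls, and these were the same 5 genes. Against 5 in the main test, 0 genes were called with upper-quartile factors, library size only, limma-voom, a mean CPM of at least 1 or at least 5, library weights and a threshold of 0.01, so that 0 were higher and 0 lower. Quantile normalisation and the legacy quasi-likelihood fit called 1 gene each, with 0 higher and 1 lower. No filter on low counts gave 8 calls (7 lower), the GC correction 9 (8 lower) and DESeq2 60 (4 higher, 56 lower, with 2214 genes given no adjusted p). The same counts held at 2-fold or more. The causes were not tested, except that a threshold of 0.01 is stricter by construction. Leaving out 1 library gave 3 to 1096 calls (0 to 485 higher, 3 to 611 lower, and 3 to 1096 at 2-fold or more), where the lone library of a group is assumed to vary as the other group does. The GC correction moved the median log2 fold change of all genes to 0.14.

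The replicate number as a block gave 76 calls (2 higher, 74 lower, 76 at 2-fold or more). Replicate differences of control and KO correlated at 0.33 across genes, but with 2 pairs and no label of a shared day the libraries share only a number, so the block was not taken into the main test. SLC35F2 had a log2 fold change of -1.65 in DESeq2 and -1.63 with the block, past the threshold in both, and -1.92 to -1.31 with 1 library left out. Of the lists, 13 were called in the main test, 8 with no filter on low counts, 8 with a mean CPM of at least 5, 0 with an estimated correlation, 0 with fry and 7 to 17 with 1 library left out. With a mean CPM of at least 5, the mesoderm and naive state lists had too few members to be tested. Chromosomes gave 0 in each setting.

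None of the genes whose sign turned was called in the main test. Without KO 2, CDKN1A (adjusted p = 0.0145) and IFITM1 (0.0475) turned and were then called as lower. The log2 fold change turned with upper-quartile factors for CALR (-0.022) and FDFT1 (-0.072), and with library size only for CALR (-0.054), CDKN1A (-0.0092), FDFT1 (-0.12), MCM3 (-0.010), MT-CO3 (-0.037), POU5F1 (-0.025), SLC35B4 (-0.028) and SNRPN (-0.011). With quantile normalisation it turned for CALR (-0.063), CDKN1A (-0.32), FDFT1 (-0.12), IFITM1 (-0.32), IFITM3 (-0.0027), LIN28A (-0.0055), MCM3 (-0.027), POU5F1 (-0.051), QTRT1 (-0.031), SLC35B4 (-0.0095) and SNRPN (-0.046). It turned for CALR (-0.019) and FDFT1 (-0.070) with a mean CPM of at least 5, for FDFT1 (-0.028) with at least 1, and for FDFT1 (-0.0079) after thinning. It turned for CDKN1A (-0.27) and IFITM1 (-0.19) in limma-voom, for CDKN1A (-0.26) and IFITM1 (-0.19) with library weights, for CDKN1A (-0.29) and IFITM1 (-0.20) with the replicate block, and for MTF1 (0.061), QTRT2 (0.0055) and SPARC (0.14) after the GC correction. With 1 library left out, the log2 fold changes of genes whose sign turned ranged as follows: BMP4 -1.92 to 0.41, CALR -0.26 to 0.45, CDKN1A -1.93 to 1.0, DNMT3B -1.19 to 0.028, FDFT1 -0.019 to 0.060, GNAS -0.072 to 0.41, H1-2 -1.42 to 0.033, H2AC6 -2.13 to 0.21, IFITM1 -1.31 to 0.90, IFITM3 -0.41 to 0.63, MCM3 -0.13 to 0.39, MT-CO1 -0.42 to 0.80, MT-CO3 -0.40 to 0.47, MYLK2 -0.21 to 1.15, NES -0.23 to 0.64, OTX2 -0.32 to 0.82, POU5F1 -0.36 to 0.45, QTRT1 -0.45 to 0.55, QTRT2 -0.56 to 0.18, SLC35B4 -0.037 to 0.22, SLC39A10 -0.23 to 0.91, SLC39A14 -1.13 to 0.25, SNRPN -0.10 to 0.33, SOX2 -0.054 to 0.34, SPARC -0.47 to 0.27, TDGF1 -0.56 to 0.095, TFCP2L1 -1.02 to 0.066 and TOP2A -0.099 to 0.60.

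Lists that turned are given with their adjusted p. They were neuroectoderm (0.99) with upper-quartile factors, neuroectoderm (0.91) with library size only, endoderm (0.74) and hypoxia and glycolysis (0.69) with a mean CPM of at least 5, and imprinted genes (0.98) with no filter. With quantile normalisation they were hypoxia and glycolysis (0.64), cholesterol synthesis (0.81), mitochondrially encoded (0.74) and replication histones (0.60). With 1 library left out, the adjusted p of lists that turned ranged as follows: replication histones 0.0093 to 0.72, cholesterol synthesis 0.00040 to 0.68, fibroblast and stromal 2.9e-09 to 0.68, hypoxia and glycolysis 4.7e-05 to 0.15, imprinted genes 0.00072 to 0.77, interferon response 0.00084 to 0.71, mitochondrially encoded 0.0011 to 0.62 and neuroectoderm 0.00093 to 0.77. Lists that were not called in the main test passed in some settings. Without KO 1, neuroectoderm (0.00093), hypoxia and glycolysis (0.0012), the interferon response (0.0074) and mitochondrially encoded genes (0.011) passed as higher. Without KO 2, neuroectoderm (0.014), hypoxia and glycolysis (4.7e-05), the interferon response (0.00084) and imprinted genes (0.00072) passed as lower, and cholesterol synthesis (0.00040) and SLC35F and nucleoside transporters (0.034) as higher. Without control 1, cholesterol synthesis (0.0098) and mitochondrially encoded genes (0.0011) passed as higher and endoderm (0.014) as lower. Without control 2, hypoxia and glycolysis (0.017) passed as higher and replication histones (0.0093) as lower. After the GC correction mitochondrially encoded genes (0.045) passed as higher. The cause of these changes was not tested. Thinning to the smallest library left 5 calls, which tests the unequal depth of the libraries, and the effect of lower or higher depth was not tested. On simulated counts the spread between libraries limited what could be called at 2-fold.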

Other observations

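The tests of explanations in this part were chosen after the results were seen, while edgeR's test over all genes was fixed beforehand. Each gene named here was also chosen after its values were seen, except SLC35F2, DNMT3B and HSPA8. SLC35F2 and DNMT3B were fixed beforehand, and HSPA8 was named for its abundance within its list. SLC30A1 also met the rule on the largest falls, which itself depends on these values. Some transcripts that are driven by or lie next to HERV-H elements, endogenous retroviruses active in human pluripotent cells, were low in both KO libraries. LINC00458 had 25.9 and 51.5 CPM in control against 1.49 and 3.95 CPM in KO (edgeR adjusted p = 0.138), and LINC01108 had 11.3 and 11.8 CPM against 0.255 and 0.497 CPM (edgeR adjusted p = 0.0588). ABHD12B had 39.3 and 40.8 CPM against 7.75 and 1.78 CPM, and SCGB3A2 had 74.4 and 55.5 CPM against 17.3 and 4.83 CPM. In edgeR's main test none of these was called over all genes, whereas DESeq2 and the replicate block called LINC00458, LINC01108, ABHD12B and SCGB3A2. No list of such transcripts was fixed beforehand, so their number among low genes was not tested. The zinc finger gene ZNF595 had 158 and 117 reads in control and 2 and 1 in KO, and the olfactory receptor gene OR52A1 had 2.73 and 2.20 CPM against 0.109 and 0.0877 CPM.

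KO 2 alone held high levels of several genes. The imprinted growth regulator DLK1 had 107 CPM in KO 2 against 0.982 CPM in KO 1 and 6.28 and 3.77 CPM in control, and LGALS1 had 160 CPM against 6.07, 6.97 and 12.8 CPM. TMSB4X had 3155 CPM in KO 2 against 638 CPM in KO 1 and 582 and 612 CPM in control. The zinc finger gene ZNF880 had 1057 reads in KO 2 and 18, 9 and 14 reads in KO 1, control 1 and control 2. In control 2 the secreted protein gene THBS1 had 533 CPM, against 90.9 CPM in control 1, 33.7 CPM in KO 1 and 18.3 CPM in KO 2.

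Metallothionein RNA and SLC30A1 were lower in both KO libraries. Reads moved only among the tested metallothioneins would leave their sum in place, but the log2 ratio of the summed CPM was -5.28, beyond the 1.37 between the controls. Since all 7 tested members were lower in both KO libraries, the sum adds little to their single values. Reads that matched several genes were left out of the counts, and a change in their share was not tested. A state behind the higher mean of the immediate early and heat shock list in control 2 is argued against as the whole cause of the metallothionein difference. Not every member of that list was raised there, since HSPA8 was lowest in control 2 (1038 CPM, against 1590 CPM in control 1). Against control 1 alone, the KO libraries had a mean difference of -4.96 log2 units in metallothioneins, where the controls differed by 1.17. The single KO libraries stood at -4.18 and -5.74. In the immediate early and heat shock list KO 1 stood at -0.69 and KO 2 at 0.27 relative to control 1, a mean of -0.21, where the controls differed by 1.53. Within each replicate number this list was lower in KO. Relative to the control mean it stood at -0.77 in control 1 and -1.46 in KO 1, and at 0.77 in control 2 and -0.49 in KO 2. Its members FOS and EGR1 were lower in KO by 0.90 and 0.92 log2 units without control 2. SLC30A1 fell by 2.50 without control 2 and was then not called. No label gives the medium or the culture batch, so a difference in zinc or other metals between the cultures was not tested. Loss of SLC35F2 itself stays open and untested.

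Some genes with steady reads in the other libraries were near 0 in a single KO library. Counting genes with at least 5 CPM in the other 3 libraries and under 0.25 CPM in 1, KO 1 had 4 (NLRP2, PUS7L, S100A6 and AC005062.1), KO 2 had 8 (CHCHD2, CRYZ, TRIM4, DUSP2, TYW3, ZNF680, ZNF732 and LINC02693) and the controls had 0 and 0. CHCHD2 had 2 reads in KO 2 where 6384 were expected from the other libraries. A library from another donor's cells cannot be excluded: GSTM1 and ERAP2, which many people do not express, differed in their on or off state in 0 of 2 cases, and cells of different donors can share both states; clonal silencing of single genes in separate KO clones was not tested.

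The 20q list was higher in KO 2, with a median of 0.512 log2 units above the mean of the other libraries, and 15 of its 19 members had their highest level there, against 36.9% of all genes considered. ID1, DNMT3B and MYLK2, inside the segment, were below the mean of the other libraries. The trend of KO 2 on GC content is argued against as the whole cause, since its removal left the median at 0.577, above the 95th percentile of random runs of neighbouring genes (0.438). Of 10000 random runs of 19 neighbouring genes, 1.8% were as high before that correction. Multiplied by the 25 lists and 4 libraries from which this list and library were picked, that share reached its limit of 100%. The list was fixed beforehand as the check of this segment, so the factor for the lists may be too strict. The multiplied share therefore does not decide the question, and chance is not excluded. Extra copies of the segment (chromosome 20, 31514410 to 32850405) in KO 2 cells therefore cannot be told apart from chance in these libraries.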
